A study of Rattus norvegicus with 4 samples.

How the data were processed

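Kidney inner medulla of Sprague Dawley rats of both sexes was sequenced in 4 libraries, 2 pools of 4 rats for each sex, so 8 rats per sex. Per the labels' protocols, rats were bought at 13 to 15 weeks of age, started the 0.49% NaCl diet at 14 to 16 weeks of age and stayed on it for 2 weeks; tissue was flash frozen, RNA was extracted with Trizol, and libraries were made with a stranded total RNA kit and sequenced from both ends on an Illumina HiSeq instrument. Groups were taken from the sample titles. A total RNA library holds unspliced and noncoding RNA beside messenger RNA.

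The submitters' processing notes name cutadapt, FastQC, TopHat2 2.1.1, StringTie, Cufflinks 2.2.1 and build rn5, without a role or order for each. Per the file headers, the main deposited table has the layout of a Cuffdiff gene comparison with 1 value per sex, in which pools 1 and 2 are joined as female and pools 3 and 4 as male. No header states the unit; the 2 value columns were read as FPKM deposited by the authors, since that is what Cufflinks reports and the values are not whole and their sums (706268 in females and 736225 in males) are not those of TPM. The normalization between libraries, the dispersion model of the test and whether strand was used are not given in the sources used here. The p-value and q-value of each locus are the authors' own and were copied. The deposited log2 fold and the test statistic, handled as a score because spreadsheet errors stand in some of its cells, are male over female, and the log2 fold was recomputed here from the FPKM values with its sign turned to female over male; the largest gap between them over tested loci above 0 in both sexes was 4.19e-05. The authors' second table gives a signed fold, also a score, for loci at least 1.5-fold apart, and its values equal those of the main table. Read counts per library and the mapping rate in percent were deposited by the authors in another table. Depth was 34552171 to 41945343 read pairs per library, and with values per sex alone no counting interval could be set on any FPKM.

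The main table has 35374 loci, of which 20307 were tested by the authors, 15046 were marked as not tested, 20 as holding too little data and 1 as failed. A symbol was given for 20240 loci; 93.7% of these have a first symbol known to the RefSeq gene table of assembly GRCr8, which was used for older names alone, with none of its positions. Several symbols were joined at 243 loci, 358 symbols stood on more than 1 row, and 24 symbols had been turned into dates by a spreadsheet, 1 of them at a called locus. These dates were not translated back. Overlapping and antisense genes cannot be told apart where strand was not used. The deposited q equals a Benjamini-Hochberg adjustment of p over the tested loci to within 5.26e-07, and a locus was called where q was under 0.05.

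The tests fixed before the data were examined assumed values per pool and were limma for genes and camera for lists. With 1 value per sex neither can be run, nor the comparison of replicate pools, and an exact permutation of 2 pools against 2 could not go below p = 0.33. The fallback fixed with them was used: values and folds with no test of their own, beside the authors' deposited test. No pseudocount and no further scaling were applied; loci at 0 in a sex have no fold. Gene lists were the 31 fixed beforehand: genes of the Y chromosome, X-linked partners, endothelin, nitric oxide and cGMP, principal cell, intercalated cell, urea transport and thin limb, osmolytes and tonicity, renin-angiotensin, prostanoids, kinins and purines, sex steroids and prolactin, clock, cholesterol synthesis, oxidative stress, interferon, complement, MHC class II, heat shock, immediate early, cell cycle, matrix and interstitium, and markers of proximal tubule, thick limb and distal tubule, podocyte, urothelium, smooth muscle, endothelium, leukocytes, red blood cells and adipocytes. A member was matched by symbol in any letter case, within joined loci as well, or by an older symbol that no other gene bears, and of several rows the one of highest mean FPKM was taken. The Y chromosome list had no locus in the table and is not analysed here. Each list with at least 3 tested members was tested with a one-sided Fisher's exact test for an excess of the authors' calls in each direction, with the tested loci that have a symbol as background and Benjamini-Hochberg adjustment over all 60 tests. The authors' p-values were also adjusted within each list. That adjustment takes no account of the number of lists, and a gene that passed it alone is not a call. The median log2 ratio of a list was set beside the medians of 10000 random lists drawn from the same 20 bins of mean FPKM, as a description.

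Named genes were chosen by a rule set beforehand. It took the 10 called genes of largest log2 difference in each direction with mean FPKM of at least 1 and a symbol that is not a placeholder. It also took Edn1, Ednra, Ednrb, Nos1, Nos2, Nos3, Scnn1a, Aqp2 and sex-linked genes where measured. Up to 4 members per list that had a call were added, called members first by fold and then those of highest mean. The test planned with this rule used log2(FPKM + 1). Ranking by fold without a pseudocount and asking for values above 0 in both sexes were not part of the rule. The part of the rule that asks for agreement of the pools could not be applied. Other genes named were chosen after their values were seen, because they passed when adjusted over the list alone, make up a count of 5 or fewer or are known markers of a list.

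The list statistics were tested on simulated data: log2 ratios of 13022 loci were permuted and 200 genes in 10 lists of 20 were shifted by 1 on the log2 scale. The median of all 10 changed lists lay outside the central 95% of random lists on the right side, as did 4.5% of 200 unchanged lists on either side. Fisher's exact test also passed for all 10, but every shifted gene had been given a very small p, so this was built in. Fisher's test was not run on the unchanged lists. Permuting the ratios also removes any correlation between genes, so its effect on either measure was not tested. The change of the ratio with expression is removed as well, so the 4.5% does not test the matching on mean FPKM. Alternatives tried were filters of mean FPKM of at least 1 and 5 and none, a pseudocount of 0.1, the log2(FPKM + 1) scale and a fold of 2 for the count of loci apart, scaling to the same median ratio and quantile normalization. Added after the data were seen were a pseudocount of 1 on genes and lists, summing rows of a symbol, leaving out loci at 0 in 1 sex, calls at q under 0.01, subsets of calls, both directions tested together, another background and symbol families without the proximal tubule list. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.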

Results

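Total RNA of the kidney inner medulla, the innermost zone of the kidney, where the urine is concentrated, was sequenced from female and male Sprague Dawley rats kept on a diet of 0.49% NaCl for 2 weeks with no other treatment. The series concerns how the sexes differ in handling dietary salt, and the deposited comparison asks which genes differ between female and male inner medulla on this diet. There were 4 libraries, 2 pools per sex, and each pool held RNA of 4 rats. The female pools had 41945343 and 37630274 read pairs and the male pools 34552171 and 36978021. The mapping rate was 89.6% and 90.3% in the female pools and 90.1% and 90.2% in the male pools. Expression was analysed here as 1 FPKM value, a fragment count scaled by transcript length and library size, per gene locus and sex, with both pools of a sex joined by the authors. The spread between pools is therefore not analysed here, the values carry no SD or n of their own, and the error measure of every comparison is the p-value, or the q-value adjusted over all tested loci, of the authors' deposited table. The p-values of that table do not go below 5.00e-05. Positions are loci as the deposited table gives them in build rn5, and a locus can be wider than the gene it is named for. They were not checked against a genome, and some chromosomes are in doubt: Tsc22d3 and Avpr2, X-linked in mammals, are listed on chromosomes 3 and 1, and Aqp2 on X. No count per chromosome is given for that reason. Of all loci, 22.8% have an interval that is listed for another locus as well, among them Lypd2 with Psca and Agxt2 with Prlr. Such an interval is not the position of a single gene.

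Among called genes with a symbol, a mean FPKM of at least 1 and values above 0 in both sexes, the 10 of largest fold were all higher in females. Adh1, an alcohol dehydrogenase (chromosome 2, 262090878 to 262102977), was at 30.1 FPKM in females and 0.566 in males, 53.3-fold apart. Slc22a7, an organic anion transporter (chromosome 9, 15821592 to 15828503), was at 8.93 and 0.225 FPKM, 39.6-fold apart. The amino acid transporter Slc7a12 (chromosome 2, 108221926 to 108514375) was at 92.7 FPKM in females and 9.70 in males. The other genes among the 10 of largest fold were Acsm1, 12.8-fold higher in females, Car15 (9.94-fold), Slc5a10 (9.56-fold), Tmigd1 (8.66-fold), Akr1c1 (8.20-fold), Kynu (7.69-fold), which acts in tryptophan breakdown, and Cyp2e1 (7.46-fold). These folds and their order depend on how low values are treated, since most of the male values were under 1 FPKM. With a pseudocount of 1, Adh1 was 19.9-fold, Slc7a12 8.76-fold, Slc22a7 8.10-fold, Car15 4.84-fold and Slc5a10 4.31-fold higher in females and stayed among the 10, while Tmigd1 (3.52-fold), Cyp2e1 (3.38-fold), Acsm1 (3.01-fold), Kynu (2.95-fold) and Akr1c1 (2.64-fold) fell behind Kap (6.91-fold), Sod3 (5.38-fold) and others. Slc22a7 and Cyp2e1 are members of the proximal tubule list, described below. All 10 passed the authors' test, with q = 0.0421 for Acsm1 and q = 0.00391 for the others in the authors' deposited table.

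Among genes higher in males the folds were smaller. Slc22a2, an organic cation transporter (chromosome 1, 51394013 to 51435104), was at 5.82 FPKM in males and 1.00 in females, 5.80-fold apart. Lypd2 (chromosome 7, 115856372 to 116157542, an interval listed for Psca as well) reached 1805 FPKM in males against 592 in females, a fold of 3.05. Gdf15, a stress-induced cytokine of the TGF-beta family (chromosome 16, 20411166 to 20413750), was at 56.9 FPKM in males and 21.2 in females. Igsf1 was 4.89-fold, the immune checkpoint receptor Lag3 4.54-fold, the locus joining Akr1c12l1 and Akr1c13 4.43-fold, the protease inhibitor Serpina1 3.77-fold, Spink13 3.43-fold, Slc27a3 3.06-fold and Agxt2 2.71-fold higher in males. With a pseudocount of 1, Slc22a2 was 3.40-fold, Lag3 2.51-fold, Igsf1 2.02-fold and Slc27a3 1.95-fold higher in males, and 7 of the 10 stayed among the 10 of largest fold. In the authors' deposited table q was 0.0320 for Slc27a3 and 0.00391 for the other 9. Members of the Akr1c and Slc22a families are close in sequence, so how reads were divided between copies is uncertain.

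**Figure D1:**
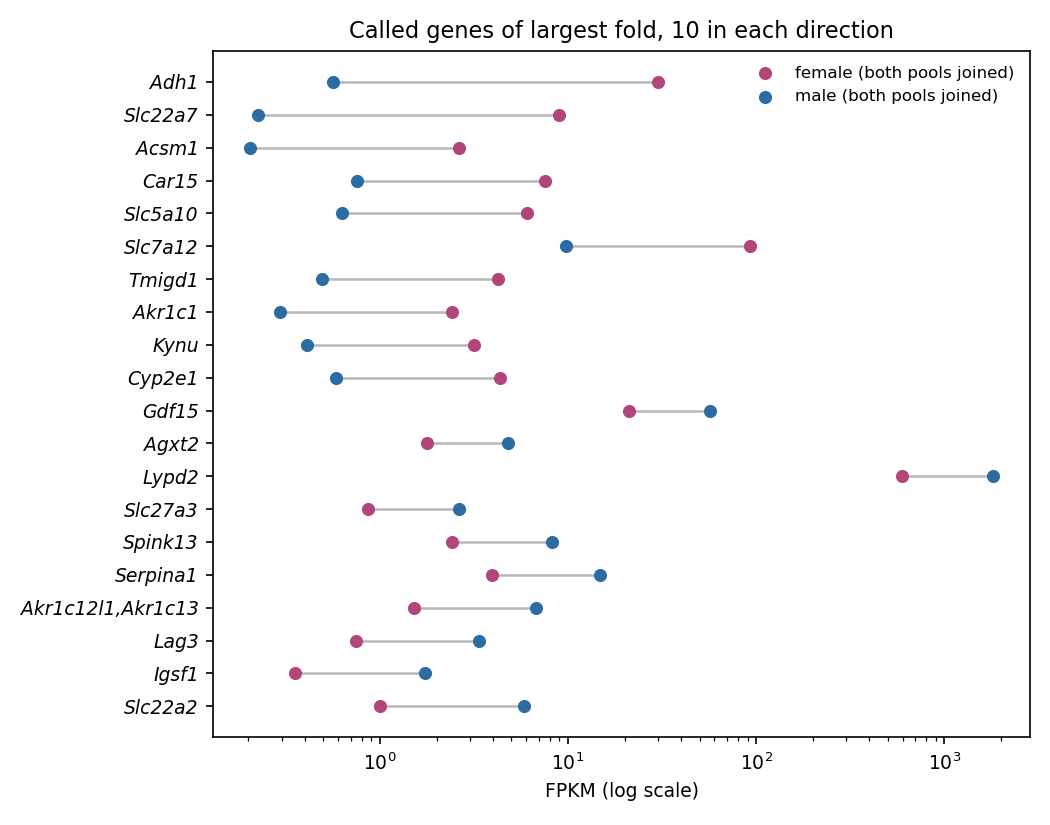
FPKM in females and in males (log axis), each over both pools of the sex joined, of the called genes with a symbol and the largest fold, 10 in each direction, with no error bars because values per pool were not used. Adh1 lies at 30.1 FPKM in females and 0.566 in males, and Lypd2 at 592 and 1805.

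Of 20307 loci tested by the authors, 476 were called at q under 0.05 in the authors' deposited table, 330 higher in females and 146 higher in males. Loci with a gene symbol held 256 higher in females and 78 higher in males, and those without one 74 and 68. Among called loci above 0 in both sexes, 187 were at least 2-fold higher in females and 52 at least 2-fold higher in males. Calls at high expression were closer to even, with 35 higher in females and 32 higher in males at mean FPKM of at least 50 and 14 and 13 above 100; whether the share depends on expression was not tested. Among tested loci of mean FPKM of at least 1 the median log2 ratio of female to male was -0.02. It changed with expression, from 0.20 for tested loci of mean FPKM under 1 to -0.05 for those above 100. For 67 called loci, 37 higher in females and 30 higher in males, the other sex was listed at 0, which in these values can be a failed estimate, and no fold was computed for them. A value of 0 in both sexes was also listed for 24 of 29 mitochondrial loci. With q adjusted again over the loci of mean FPKM of at least 5 alone, 236 loci were called.

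**Figure D2:**
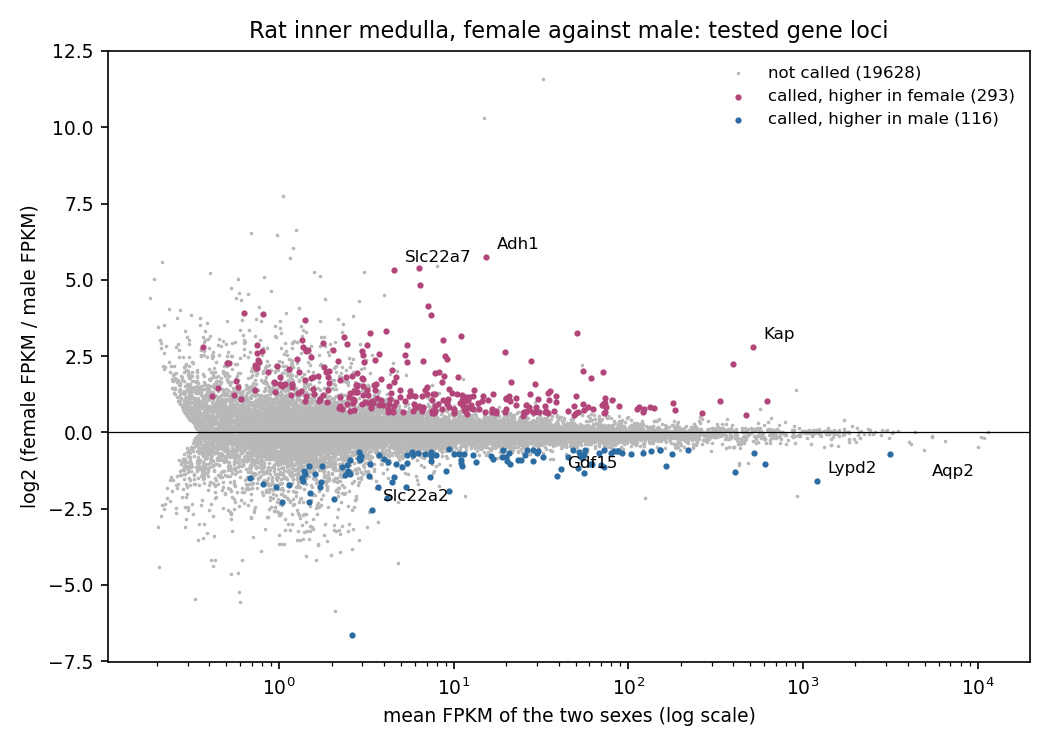
Log2 ratio of female to male FPKM against the mean FPKM of the sexes (log axis) for tested loci above 0 in both; each point is 1 locus, coloured where q was under 0.05 in the authors' deposited table. Of the points, 293 are called higher in females and 116 higher in males, with Adh1, Slc22a7 and Kap on the female side and Lypd2, Slc22a2 and Gdf15 on the male side.

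The 31 gene lists were fixed before the data were examined, and 30 had at least 3 tested members. An excess of calls over the 13036 tested loci with a symbol, by a one-sided Fisher's exact test with Benjamini-Hochberg adjustment over 60 tests, was found for 4 lists towards females (proximal tubule, extracellular matrix and interstitium, urothelium, MHC class II) and for 3 towards males (clock, osmolytes and tonicity, immediate early genes). Genes of a list are not independent of each other, so these p-values are too small. This test was chosen after the layout of the data was known. Where genes are said below to pass when adjusted over a list alone, the number of lists was not corrected for. Of the 30 lists, 17 had a median log2 ratio above the central 95% of 10000 random lists matched on expression, 4 below it (clock, interferon, cell cycle, and sex steroids and prolactin) and 9 within it.

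**Figure D3:**
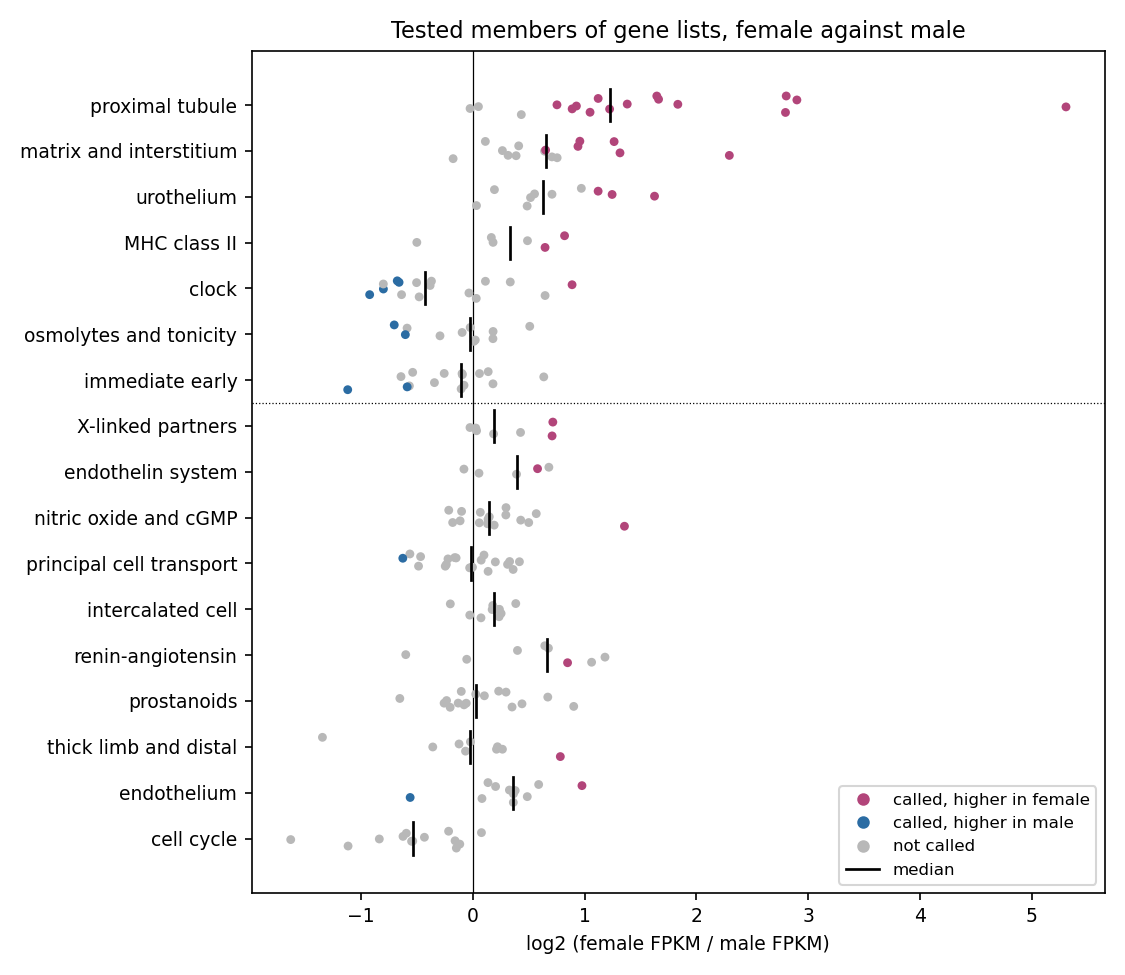
Log2 ratio of female to male FPKM of the tested members of 17 gene lists that are above 0 in both sexes; each point is 1 gene, coloured where q was under 0.05 in the authors' deposited table, and the bar is the list's median. The 7 lists above the dotted line had an excess of calls; the proximal tubule median lies at 1.22 and the clock median at -0.43.

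In the endothelin system, which lowers sodium reabsorption in the collecting duct, 1 of 5 tested genes was called. Ednrb, the endothelin B receptor (chromosome 15, 91476330 to 91555910), was at 58.4 FPKM in females and 39.1 in males, 1.49-fold apart with q = 0.0421 in the authors' deposited table. Edn1, the gene of endothelin-1 (chromosome 17, 24118008 to 24124009), was at 2.76 FPKM in females and 2.92 in males (q = 0.999 in the authors' deposited table). Ednra was at 1.85 and 1.15 FPKM (q = 0.171 in the authors' deposited table), Edn3 at 23.4 and 17.8, and Ece1, a converting enzyme, at 18.3 and 17.6. Adjusted over the list alone, 2 genes passed, Ednrb and Ednra, both higher in females. The list's excess of calls did not pass (adjusted p = 0.364 by Fisher's exact test). The list's median log2 ratio of female to male was 0.39, above the range of matched random lists (-0.20 to 0.28). That of endothelial markers was 0.36.

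Of 16 tested genes of nitric oxide and cGMP signalling, 1 was called. Ddah1, which breaks down inhibitors of nitric oxide synthase (chromosome 2, 270160833 to 270289319), was at 3.87 FPKM in females and 1.51 in males, 2.56-fold apart with q = 0.00391 in the authors' deposited table. Nos1 was at 4.05 FPKM in females and 4.69 in males, and Nos3 at 7.62 and 6.21, with q = 0.999 and q = 0.762 in the authors' deposited table. NOS2 was not tested by the authors, at 0.0253 FPKM in females and listed at 0 in males. Adjusted over the list alone, 2 genes passed towards females, Ddah1 and Ass1. Ass1, an enzyme of arginine synthesis, was at 24.8 against 16.7 FPKM with q = 0.109 in the authors' deposited table. The proximal tubule, whose list moved the same way with a median of 1.22, also expresses both, so they cannot be assigned to a change of nitric oxide signalling.

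Of 20 tested genes of the principal cell, among them those of sodium and water transport, 1 was called. Tsc22d3, also known as Gilz and induced by corticosteroids, was at 165 FPKM in males and 107 in females (q = 0.00703 in the authors' deposited table). Aqp2, the vasopressin-regulated water channel, was at 8463 FPKM in females and 11693 in males, with q = 0.923 in the authors' deposited table. Scnn1a, a subunit of the epithelial sodium channel, was at 12.1 and 11.5 FPKM (q = 0.999 in the authors' deposited table), and Fxyd4 at 4006 and 5915 FPKM (q = 0.105 in that table of the authors). Adjusted over the list alone, 3 genes passed, all higher in males: Tsc22d3, Fxyd4 and Sgk1 (q = 0.132 for Sgk1 in the authors' deposited table). None of the 10 tested markers of intercalated cells was called, but 8 of them were above 0 in log2 ratio, with a median of 0.19 against -0.15 to 0.04 in matched random lists. None of the 17 tested prostanoid genes was called; Ptgs2, the inducible cyclooxygenase, was at 2.67 FPKM in females and 1.43 in males with q = 0.0530 in the authors' deposited table. In opposite directions, Ptgs2 passed when adjusted over the list alone, and so did Ptgds, a prostaglandin D2 synthase, at 18.2 FPKM in females and 28.5 in males.

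Of 8 tested genes of urea transport and thin limb, Sptssb was called, at 25.1 FPKM in females and 14.6 in males (q = 0.00391 in the authors' deposited table). Slc14a2, the urea transporter of the inner medullary collecting duct, was at 229 and 297 FPKM with q = 0.452 in the authors' deposited table. The osmolyte and tonicity list had 2 of 11 tested genes called, both higher in males (adjusted p = 0.0225 by Fisher's exact test). These were S100a4, a calcium-binding protein (chromosome 2, 209431369 to 209433679), at 3897 FPKM in males and 2396 in females, and Slc38a2, a transporter of neutral amino acids, at 101 and 66.2, with q = 0.00703 and q = 0.0123 in the authors' deposited table. Akr1b1, the aldose reductase that makes sorbitol, was at 3218 FPKM in females and 3270 in males. The median log2 ratio of the list was -0.02. With calls taken at q under 0.01 its excess was lost (adjusted p = 0.414).

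Of 8 tested genes of the renin-angiotensin system, Anpep, an aminopeptidase, was called at 14.5 FPKM in females and 8.05 in males (q = 0.00391 in the authors' deposited table). Agtr1a, an angiotensin II receptor, was at 6.79 and 4.34 FPKM with q = 0.143 in the authors' deposited table. Adjusted over the list alone, 5 genes passed, all higher in females: Anpep, Enpep, Agtr1b, Agtr1a and Mme. Apart from Anpep none of them was called, with q = 0.0711 for Enpep, 0.0920 for Agtr1b and 0.321 for Mme in the authors' deposited table. Anpep, Enpep and Mme are also peptidases of the proximal tubule brush border, and the proximal tubule list moved the same way with a median of 1.22, so these cannot be assigned to a change of the renin-angiotensin system. Among 9 tested kinin and purine genes, Adora2a, an adenosine receptor, was called at 12.1 against 6.82 FPKM, higher in females. Of 14 tested genes of superoxide production and antioxidant defence, 2 were called. Sod3, the extracellular superoxide dismutase (chromosome 14, 61071312 to 61083911), was at 34.03 FPKM in females and 5.51 in males, 6.18-fold apart, and Gclc, which acts in glutathione synthesis, at 95.1 and 54.0; both had q = 0.00391 in the authors' deposited table. The proximal tubule expresses these 2 as well. None of these 3 lists had an excess of calls (adjusted p = 0.463, 0.467 and 0.199 by Fisher's exact test). The median log2 ratio of the renin-angiotensin list was 0.66, against -0.16 to 0.32 in matched random lists. That of kinins and purines was 0.14 (-0.17 to 0.34) and that of antioxidant defence and superoxide production 0.10 (-0.13 to 0.06).

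Y-linked genes and Xist are not analysed here. Of 7 tested X-linked genes that have a Y-linked partner, 2 were called higher in females (adjusted p = 0.0567 by Fisher's exact test, and 0.0382 over loci of mean FPKM of at least 5 alone). Kdm6a, a histone demethylase (chromosome X, 5577375 to 5731815), was at 9.41 FPKM in females and 5.72 in males, and Eif2s3, a translation initiation factor, at 46.8 and 28.6, with q = 0.00391 and q = 0.00703 in the authors' deposited table. DDX3X, at 79.3 and 77.8 FPKM, and Uba1, at 70.9 and 72.2, were not called. None of the 9 tested genes of sex steroid and prolactin signalling was called. Prlr, the prolactin receptor, was at 0.409 FPKM in females and 1.81 in males with q = 0.167 in the authors' deposited table. Adjusted over the list alone, Prlr passed together with Fkbp5 (q = 0.118 in the authors' deposited table), both higher in males.

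Genes of the proximal tubule, a segment of cortex and outer medulla, held a larger share of calls than any of the other tested lists. Of 17 tested members 14 were called, all higher in females, against 1.96% of the tested loci with a symbol (adjusted p = 3.44e-20 by Fisher's exact test). Kap, an androgen-regulated protein of the proximal tubule (chromosome 4, 230009067 to 230209088), was at 910 FPKM in females and 131 in males, a fold of 6.95. Whether androgen has a part in this difference was not tested. Cubn, a receptor for protein uptake (chromosome 17, 82205508 to 82425565), was at 2.40 and 0.344 FPKM. With Slc22a7 and Cyp2e1, these were the 4 members of largest fold without a pseudocount, each with q = 0.00391 in the authors' deposited table. Slc34a1, the sodium-phosphate cotransporter, was at 16.2 FPKM in females and 9.63 in males and was also called. Miox, at 21.1 and 20.3 FPKM, Pck1, at 3.94 and 4.01, and the locus joining Cyp4a2, Cyp4a8 and Cyp4b1, at 78.4 and 58.0, were not called. Adjusted over the list alone, 15 members passed. The median log2 ratio of the list was 1.22, above the central 95% of 10000 random lists matched on expression, which ran from -0.11 to 0.14.

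Of the markers of the thick limb and distal tubule, Egf was called at 7.61 FPKM in females and 4.42 in males (q = 0.00970 in the authors' deposited table), as the only one of 9 tested. Egf passed towards females when adjusted over the list alone, and Calb1 of the distal convoluted tubule, at 0.477 FPKM in females and 1.21 in males, towards males. Umod, uromodulin of the thick limb, was at 830 FPKM in females and 904 in males, and SLC12A1, its sodium transporter, at 231 and 199, with q = 0.999 and q = 0.920 in the authors' deposited table. The median log2 ratio of these markers was -0.02, within the range of matched random lists (-0.16 to 0.15), but 0.10 over members of mean FPKM of at least 1 and 0.21 over those of at least 5. Umod and SLC12A1 at such levels leave open that the pools of both sexes held some outer medulla. Values given here for inner medulla are those of the tissue as dissected and may be of mixed tissue. Of the podocyte list, Podxl, which endothelium also expresses, was called at 29.7 against 20.3 FPKM, and the other 4 tested members were not.

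The list of extracellular matrix and interstitial cells held an excess of calls towards females, with 6 of 15 tested members called (adjusted p = 7.00e-06 by Fisher's exact test) and 8 when adjusted over the list alone. Col1a1, a chain of collagen I, was at 4.00 FPKM in females and 1.60 in males, and Lum, a matrix proteoglycan, at 1.27 and 0.259. The growth factor receptor Pdgfra was at 14.8 and 6.17 FPKM. FN1, the gene of fibronectin (chromosome 9, 78674434 to 78747362), was at 96.5 and 49.7 FPKM. The authors' deposited table gave q = 0.0238 for Lum and q = 0.00391 for the other 3. Sparc, at 118 and 109 FPKM, and Vim, at 118 in females and 133 in males, were not called. Beside these genes, none of 7 tested smooth muscle markers was called, although 2 passed when adjusted over the list alone, and their median log2 ratio was 0.36.

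Urothelial genes had 3 of 10 tested members called, all higher in females (adjusted p = 0.0122 by Fisher's exact test), and 6 when adjusted over the list alone. Upk2, a uroplakin of the umbrella cell membrane (chromosome 8, 47391875 to 47393868), was at 10.7 FPKM in females and 4.49 in males, Upk1b at 4.99 and 2.30, and the locus joining Krt5 and Krt73 at 2.93 and 0.949. Their q in the authors' deposited table was 0.0123, 0.00703 and 0.0148. The abundant Psca, at 945 and 826 FPKM, and Krt7, at 252 and 246, were not called. Among loci of mean FPKM of at least 5 the excess was lost (adjusted p = 0.276), since that leaves out Upk1b and Krt5, and it was lost with calls taken at q under 0.01 as well (adjusted p = 0.503).

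Of the MHC class II list, 2 of 6 tested genes were called, both higher in females (adjusted p = 0.0469 by Fisher's exact test), and 3 when adjusted over the list alone. RT1-Db1 (chromosome 20, 6167758 to 6177326) was at 34.5 FPKM in females and 19.5 in males and RT1-Da at 88.3 and 56.4, with q = 0.00391 and q = 0.0173 in the authors' deposited table. Cd74, the invariant chain, was at 302 and 215 FPKM and RT1-Bb at 16.1 and 14.2, neither of them called. Reads of RT1 genes can be shared between close copies. Of 11 tested leukocyte markers, Cd3e of T cells was called at 2.15 against 0.651 FPKM, higher in females, and their median log2 ratio was 0.53; 5 passed when adjusted over the list alone. Of 12 tested complement genes, C1r was called at 63.0 against 34.4 FPKM, higher in females, and C2 at 181 against 122, higher in males. Adjusted over the list alone, 4 passed towards females and 1 towards males. In log2 ratio 10 of the 12 were above 0, with a median of 0.53 against -0.13 to 0.20 in matched random lists. With calls taken at q under 0.01 the MHC class II excess was lost (adjusted p = 0.465).

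Among 11 tested endothelial markers, Plvap of fenestrated endothelium was called higher in females, at 240 against 122 FPKM, and Vwf higher in males, at 11.2 against 7.62. The authors' deposited table gave q = 0.00391 and q = 0.0421 for these. Fabp4, which adipocytes and capillary endothelium express, was called at 92.5 FPKM in females and 49.96 in males, and Adipoq, at 4.14 and 2.67, was not. None of the 4 tested red blood cell loci was called; the locus joining Hba1 and Hba2 was at 761 FPKM in females and 550 in males (q = 0.125 in the authors' deposited table). No excess of calls was found for the endothelial, leukocyte, adipocyte, podocyte, thick limb, smooth muscle or blood lists. Apart from the thick limb list, their medians nonetheless lay above the central 95% of matched random lists: 0.36 for endothelium (upper bound 0.09), 0.53 for leukocytes (0.33), 0.63 for adipocytes (0.43), 0.55 for podocytes (0.53), 0.36 for smooth muscle (0.26) and 0.37 for blood (0.34).

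Circadian clock genes were called in both directions. Of 16 tested members, 4 were called higher in males (adjusted p = 4.09e-05 by Fisher's exact test) and 1 higher in females. Per2, a repressor of the clock (chromosome 9, 98231203 to 98273371), was at 9.74 FPKM in males and 5.14 in females, 1.89-fold apart. Its relative Per3 was at 9.07 and 5.75 FPKM. The clock-controlled transcription factors Dbp (chromosome 1, 102766761 to 102771674) and Tef were at 150 against 93.9 and at 25.2 against 14.5 FPKM. Npas2, an activator of the clock, was higher in females at 4.87 against 2.63 FPKM. The q of the authors' deposited table was 0.00970 for Per2 and Per3, 0.00703 for Dbp and 0.00391 for Tef and Npas2. ARNTL, the partner of Npas2, was at 9.72 FPKM in females and 6.21 in males with q = 0.0586 in the authors' deposited table. Adjusted over the list alone, 7 members passed towards males and 2 towards females. Nr1d1, at 70.3 FPKM in females and 65.0 in males, and Bhlhe40, at 20.5 and 20.1, did not. Of the 16 tested members, 11 were below 0 in log2 ratio and 5 above. The time of day at which tissue was collected is not given in the sources used here.

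Of 15 tested immediate early genes, which respond within minutes to stimuli and to tissue handling, 2 were called, both higher in males (adjusted p = 0.0353 by Fisher's exact test), and 4 passed when adjusted over the list alone. Fos (chromosome 6, 116249152 to 116252608) was at 15.2 FPKM in males and 7.01 in females and Btg2 at 87.8 and 58.5, with q = 0.00391 and q = 0.0284 in the authors' deposited table. Junb, at 64.0 and 59.9 FPKM, and Ier3, at 237 and 160, were not called. With calls taken at q under 0.01 the excess was lost (adjusted p = 0.465). Hsph1 was called as 1 of 10 tested heat shock genes, at 183 FPKM in males and 123 in females, and Mx1 as 1 of 17 tested interferon-stimulated genes, at 57.5 and 38.6; the median of the interferon list was -0.16, below the range of matched random lists (-0.12 to 0.08). None of 16 tested cholesterol synthesis genes and none of 13 tested cell cycle genes was called, with 0 passing when adjusted over either list alone; the median log2 ratio of the cell cycle genes was -0.54, below the central 95% of matched random lists, which ran from -0.14 to 0.41. It was -0.23 with a pseudocount of 1, -0.22 over members of mean FPKM of at least 1 and -0.16 over those of at least 5, so its size came from members of low expression. The cholesterol synthesis median, 0.08, lay just above its range of -0.11 to 0.07.

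A second deposited table holds the loci that the authors took as at least 1.5-fold apart, 8418 in all, 4913 higher in females and 3505 higher in males. Of these, 2413 were listed at 0 in 1 sex and so have no fold, 50.2% were not tested by the authors, 71.1% had a mean FPKM under 1, and 466, with 67 at 0 in 1 sex among them, were called in the authors' deposited table. With mean FPKM of at least 1 the table holds 2435 loci, 1357 higher in females and 1078 higher in males, of which 117 were at 0 in 1 sex. These counts carry no test.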

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

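No paired analysis was possible because the deposited values join both pools of each sex, so the columns carry no pool number. For the same reason limma (with and without trend or robust fitting), camera, fry, the replicate block, the leave-one-out runs and the comparison of pools were not run, nor DESeq2 or edgeR, which need counts. Calls at q under 0.01, subsets of calls, both directions together, the other background, summing rows of one symbol, leaving out loci at 0 in 1 sex and the pseudocount of 1 on named genes and lists were chosen after seeing the data. The count of 476 called loci was 236 (158 higher in females, 78 in males) with q adjusted over loci of mean FPKM of at least 5, where fewer loci are tested, and 314 at q under 0.01, with 90 higher in males. Calls with a symbol held 78 higher in males. Under the other 4 alternatives it ran from 409 to 466, and the share higher in females from 66.9% to 76.6% over all 7, but calls at mean FPKM of at least 50 were 35 and 32. The number of loci at least 1.5-fold apart, 2435, depended on the treatment of low values and on the fold asked for: it was 8418 with no filter, 480 with mean FPKM of at least 5, 1440 on the log2(FPKM + 1) scale and 1087 at 2-fold, against 2450 after scaling to the same median ratio, 2434 with rows of one symbol summed and 2318 without loci at 0 in 1 sex. Of the 7 lists with an excess of calls, the count stayed 7 with either filter, although at mean FPKM of at least 5 the urothelial excess was lost (adjusted p = 0.276) and that of the X-linked partners passed (adjusted p = 0.0382), was 8 with all tested loci as background, adding the X-linked partners (adjusted p = 0.0393), and fell to 4 with both directions tested together and to 3 with calls at q under 0.01, which leaves proximal tubule, matrix and clock. No called gene changed sign under quantile normalization, and the q of the 112 named genes tested at mean FPKM of at least 1 stayed on its side of 0.05. A pseudocount of 1 moved the fold of 17 of 113 named genes by more than 1.5 times; their highest value in the lower sex was 1.00 FPKM. Of tested loci with a mean FPKM under 1, 1.84% were called, against 2.59%, 2.18%, 2.59% and 2.54% in the ranges up to 5, 25 and 100 and above; what depth limits was not tested.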

Other observations

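The gene families and every test in this part were chosen after the values were seen. Among 174 families of symbols with at least 10 tested members, 3 had an excess of the authors' calls by a one-sided Fisher's exact test with Benjamini-Hochberg adjustment: the Slc22a transporters of organic ions, with 7 of 17 called higher in females and 1 higher in males (adjusted p = 5.91e-07), solute carriers as a whole, with 20 and 5 of 265 (adjusted p = 1.70e-06), and collagens, with 5 and 1 of 32 (adjusted p = 0.00809). These are not independent findings. Collagens overlap the matrix and interstitium list, which holds Col1a1, Col1a2, Col3a1, Col4a1, Col5a1 and Col6a1, and were not tested without its members. Slc22a is part of the solute carriers, and both overlap the proximal tubule list, which holds Slc22a6, Slc22a7, Slc22a8, Slc34a1, Slc7a13 and Slc13a3, all of them called. With the members of that list left out, 4 of 14 tested Slc22a genes were called higher in females and 1 higher in males (adjusted p = 0.00192), and 14 and 5 of 259 solute carriers (adjusted p = 0.00192), some of which are known from the proximal tubule too. Slc22a12, the urate transporter, was at 12.5 FPKM in females and 3.23 in males, and Slc22a24, Slc22a25 and Slc22a13 were at 3.54, 2.53 and 2.59 FPKM in females against 0.548, 0.390 and 0.470 in males. Slc22a2 was the called member that was higher in males. Col17a1, of epithelial attachment to the basement membrane, was at 2.45 FPKM in females and 0.691 in males and Col12a1 at 20.8 and 12.3, whereas Col11a1 was higher in males at 9.99 against 5.96.

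Other called genes are given as values. The keratin and Cyp families had no excess of calls (adjusted p = 0.137 and 0.199 by Fisher's exact test). The Igfbp and Sult families had fewer than 10 tested members and were not tested. The basal keratins Krt14 and Krt15 were at 5.92 and 12.2 FPKM in females and 1.77 and 6.19 in males. The insulin-like growth factor binding proteins Igfbp1, Igfbp5 and Igfbp6 were at 51.1, 451 and 38.0 FPKM in females and 19.8, 223 and 21.3 in males. Cyp1a1, a target of the aryl hydrocarbon receptor, was at 1.38 FPKM in females and 0.220 in males, and Cyp4f1 at 6.39 and 1.07. Sult1c2a, a sulfotransferase on 2 rows, was at 46.6 FPKM in females and 9.16 in males on the more abundant one. All of these had q under 0.05 in the authors' deposited table.

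Of the proximal tubule list, 14 of 17 tested members were called higher in females, and sex and dissection go together in this design. A larger share of proximal tubule in the female pools as the only cause would raise these genes by about 1 factor. This holds only for a uniform segment that is their sole source. The 95% intervals of 8 of the 17 tested members left out the list's median log2 ratio of 1.22, 4 above it and 4 below. These intervals were drawn from the authors' p on a normal scale. They are too wide where p is at its floor, and their width there follows the log2 ratio alone. The lower bound for Slc22a7, 2.74, lay above the upper bounds of 13 members, and Slc22a2, another proximal tubule transporter, was called higher in males. Of the 4 below the median, Pck1 is also on the adipocyte list and the Cyp4a2 locus joins other symbols. Other sources or unequal shares of parts of the segment would also spread the folds, so the spread cannot exclude a larger share. Outer medulla carried along with the female tissue may still account for part of the rise. The median log2 ratio of thick limb and distal markers was -0.021, and 0.10 and 0.21 over those of mean FPKM of at least 1 and 5. Umod, at 830 FPKM in females and 904 in males, is so abundant in both sexes that a small share would not show. Its level also leaves open that the pools of both sexes held outer medulla. Of the markers with a low baseline, Calb1, at 0.477 FPKM in females and 1.21 in males, and Slc12a3, at 0.882 and 1.13, were not higher in females, whereas Egf was called higher in females at 7.61 against 4.42 and the podocyte list had a median of 0.55, so markers of tissue outside the inner medulla go both ways and decide nothing about outer medulla or cortex. A share of outer medulla and a sex difference in the expression of these genes, which was not tested, cannot be told apart here.

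Clock genes lay mostly on opposite sides, with the median log2 ratio of 3 activators 1.15 above that of 13 repressors and outputs. Not all members followed. Among the 13, Nr1d1 at 70.3 FPKM in females and 65.0 in males, Bhlhe40 at 20.5 and 20.1 and Hlf at 1.55 and 1.59 were close to even. The activator Clock, at 1.68 and 1.33 FPKM, was not called. A gap between the medians is what pools collected at different times of day could give, and a clock that differs with sex would give it too. These explanations cannot be told apart without collection times, which are not given in the sources used here. Higher glucocorticoid exposure in the male pools is a candidate explanation for Tsc22d3, for Per genes and for Zbtb16, at 6.34 FPKM in males and 3.07 in females. The median log2 ratio of 13 tested glucocorticoid-responsive genes was -0.26, with 2 called higher in males and Cebpd called higher in females at 15.1 against 7.19 FPKM, and members that go both ways leave it open.

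For 67 called loci the other sex was listed at 0, and 64 of them have no symbol. Their median FPKM in the sex above 0 was 2.03. Of all tested loci with 1 sex listed at 0, 24.8% were called, against 2.04% of the other tested loci. Reads of the Y chromosome, for which no locus was listed, would give loci with females at 0 if placed elsewhere. Of the 67 loci, 30 were of that kind and 37 had males at 0 (exact two-sided binomial p = 0.464). Such reads could not give the 37. Whether they gave any of the 30 stays open, since the test compares the 2 counts with an even split and not their sources. Estimates that drop to 0 in short loci are a possible explanation: the median length of the 64 was 287.5 bp against 3372.5 bp for the 78 other called loci without a symbol. Short loci transcribed in 1 sex alone would give the same, so without values per pool these cannot be told apart here.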
